A study of Homo sapiens with 15 samples.

How the data were processed

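Total RNA of PATU-8988T cells was measured by RNA sequencing in 15 libraries, 3 in each of 5 groups: DMSO, THZ1 for 4 h, THZ1 for 24 h, YKL-5-124 for 4 h and YKL-5-124 for 24 h. Groups and replicate numbers were taken from the sample labels. The authors deposited 1 table of raw counts per Ensembl gene, with a column for each library and no normalization. Per the submitters' processing notes, STAR 2.6.1d, featureCounts 1.5.0-p3, DESeq2 1.24.0 and the GRCh38 build were used. The strand setting of the counting, its treatment of reads with several matches and its filters are not given in the sources used here. Reads of overlapping genes on opposite strands therefore cannot be told apart, and 59 of the 215 genes named by the rule given here overlap another tested gene. The same caution holds for multigene families such as histones. The table held 58676 genes, 0 rows naming no gene and 0 columns of no sample. Symbols, positions, exonic lengths and biotypes came from the table; among the genes tested, 10 repeated the symbol of another gene ID. The length and GC content of each gene's longest transcript came from GENCODE release 29, in which 100% of the gene IDs were found and 95.3% of genes had the same start and end.

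Depth ranged from 15567057 to 18114103 counts in THZ1 24 h, 18464691 to 21749763 in THZ1 4 h, 19651529 to 20517571 in DMSO, 18929158 to 22869590 in YKL-5-124 4 h and 18373599 to 22184092 in YKL-5-124 24 h. Shares of counts were computed over 86 protein-coding genes with symbols of ribosomal proteins and over 37 genes of the mitochondrial genome. CPM, the normalized counts, used the totals over the genes tested multiplied by TMM factors. Within each group no pair of libraries agreed within sampling noise (chi-square per degree of freedom 4.28 to 82.6), so none was merged with another as a copy. This does not show that they came from separate cultures.

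Of the 58676 genes, 30731 had at least 1 count and 14461 passed filterByExpr (minimum count 10, minimum total 15), which kept 99.9% of the counts. Of these 12212 were protein-coding. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3), fitted to all 15 libraries with group as the only factor and TMM scaling, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. It was applied to 8 comparisons between groups and to the interaction of compound and time. Standard errors and 95% intervals came from the same fit. For named genes with few counts in a group, the ratio to DMSO was given with an exact binomial 95% interval. Such intervals cover counting error only. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, adjusted by Benjamini-Hochberg over lists and comparisons, where at least 5 members were tested. Of 198 such tests, 67 passed at the preset correlation, and 29 of these also passed with an estimated one.

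There were 23 gene lists, which, like the tests, most of the other settings and the rule for named genes, were fixed before the data were examined. They covered G1/S and DNA replication; G2/M and mitosis; cyclins, CDK inhibitors and RB family; homologous recombination and Fanconi genes; ATR checkpoint; p53 targets; BCL2 family; immediate-early and short-lived transcripts; ERK pathway output; NF-kB targets; interferon-stimulated genes; ribosome biogenesis and MYC targets; Pol II kinases and general transcription; ATF4 and the unfolded protein response. The rest were heat shock, cholesterol synthesis, hypoxia and glycolysis, epithelial and ductal genes, mesenchymal genes, stromal and immune markers, acinar, islet and liver markers, replication-dependent histones and mitochondrially encoded mRNAs. For each comparison with DMSO the rule named the 4 largest rises and the 4 largest falls by log2 fold change among protein-coding genes with an adjusted p under 0.05, a mean CPM over the 15 libraries of at least 5 and the 3 treated libraries all on the same side of the DMSO libraries. It also named up to 2 called members of each list with the largest absolute change at a mean CPM of at least 1. For a list with called members in both directions, it named up to 2 in each direction. It named CDK7, CDK12 and CDK13 whatever their p. Between compounds it took the 4 largest differences on each side, 1 member per list and the same kinases, and for the times and the interaction the 3 largest on each side, without the rule on sides for the interaction. Genes named in 1 comparison were also given in others for contrast. Some genes that the rule names are not reported here.

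The test was tested on simulated data drawn from the DMSO means and the library sizes and dispersions of the real libraries, with a seeded set of the 13952 genes changed in each treated group. It recovered 95.3% of 4-fold, 74.5% of 2-fold and 25.9% of 1.5-fold changes for THZ1 4 h against DMSO, and 98.6%, 70.4% and 28.8% for THZ1 24 h. For YKL-5-124 4 h against DMSO it recovered 98.7%, 73.7% and 18.8%, and for YKL-5-124 24 h 94.4%, 66.1% and 8.57%. The wrong direction was called for 0 changed genes, and 6, 9, 8 and 6 unchanged genes were called in the same order. For THZ1 24 h only 59, 71 and 70 genes were changed 1.5-, 2- and 4-fold, upwards or downwards at random. In the real libraries 76.1% of genes were called in that comparison, so errors of scaling there are not covered. Genes were drawn independently, so variation that genes share within groups is not covered either.

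The other settings tried were DESeq2 1.42.0, RLE and upper-quartile factors, library totals, other low-count filters, a fit to only the groups compared, library sizes and factors without mitochondrially encoded genes, protein-coding genes only, the replicate number as a block, leaving out each library, and a fold threshold of 2. For gene span, the planned test was the slope of each treated library's log2 change on log10 span, compared between compounds by a two-sided exact permutation test. Chosen after seeing the data were a covariate for each library's slope on transcript length and the use of ribosomal protein mRNAs as the scaling reference. That slope was measured on deviations from the group mean. The covariate can therefore take up spread within groups but no difference between groups. Overlaps between comparisons that share the DMSO libraries were set beside 20 simulations of unchanged groups and beside the product of the list sizes divided by the number of genes.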

Results

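The samples were 15 libraries of total RNA from PATU-8988T, an established human pancreatic cancer cell line. The cells were treated with THZ1 or with YKL-5-124, which the series describes as inhibitors of CDK7. CDK7 is the kinase of the general transcription factor TFIIH, which phosphorylates RNA polymerase II and activates other cyclin-dependent kinases. Each compound was given at 100 nM for 4 h or 24 h, and control cells received 0.1% DMSO. There were 5 groups of 3 libraries each, with 15567057 to 22869590 counts per library. The DMSO libraries carry no time in the labels, so the same 3 served as control at both times, and time in culture was not separated from time of treatment. The labels number the replicates without saying whether they came from separate cultures, so p-values measure only the spread between these samples.

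The make-up of the libraries differed most after 24 h of THZ1. Transcripts of ribosomal protein genes took 22.0% ± 1.18 of the counts there (SD, n = 3 libraries), against 10.7% ± 1.43 in DMSO, 12.8% ± 1.95 after 4 h of THZ1, 11.1% ± 1.01 after 4 h of YKL-5-124 and 7.92% ± 1.22 after 24 h of YKL-5-124. Genes of the mitochondrial genome took 4.08% ± 0.539 after 24 h of THZ1, 1.56% ± 0.524 after 4 h of THZ1 and 1.01% ± 0.214 in DMSO. The 20 most abundant genes took 15.5% ± 0.327 after 24 h of THZ1 and 8.40% ± 0.784 in DMSO. For each of these shares, every THZ1 24 h library lay above every library of the other groups. With these group sizes, 3 libraries against 3 cannot give an exact permutation p below 0.1. The TMM scaling factors, which assume that most genes do not change, averaged 0.544 after 24 h of THZ1, 0.994 after 4 h of THZ1 and 1.19 in DMSO.

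Fold changes are therefore relative to a scaling, which is TMM unless another is named. Scaling to library totals in place of TMM moved the median log2 fold change of all genes by −1.13 for THZ1 24 h against DMSO, −0.25 for THZ1 4 h and 0.14 for YKL-5-124 24 h. Taking the summed counts of ribosomal protein mRNAs as the reference moved it by −2.19, −0.51 and 0.58, in the same order. For YKL-5-124 4 h against DMSO neither moved it by more than 0.1, at −0.01 and −0.09. For THZ1 24 h, RLE factors moved it by 0.32, upper-quartile factors by 0.39 and DESeq2 by 0.28. The share of ribosomal protein mRNAs itself differed between the groups, so a value against them is a change relative to theirs. Of the 14461 genes tested, 4657 were higher and 6352 lower in THZ1 24 h than in DMSO under TMM. Of these calls 3560 and 5196 differed at least 2-fold. The split was 5449 and 5457 under RLE factors, 5615 and 5284 under upper-quartile factors and 5276 and 5509 by DESeq2 over the same genes. It was 2261 and 9374 under library totals and 572 and 11708 against ribosomal protein mRNAs.

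**Figure D1:**
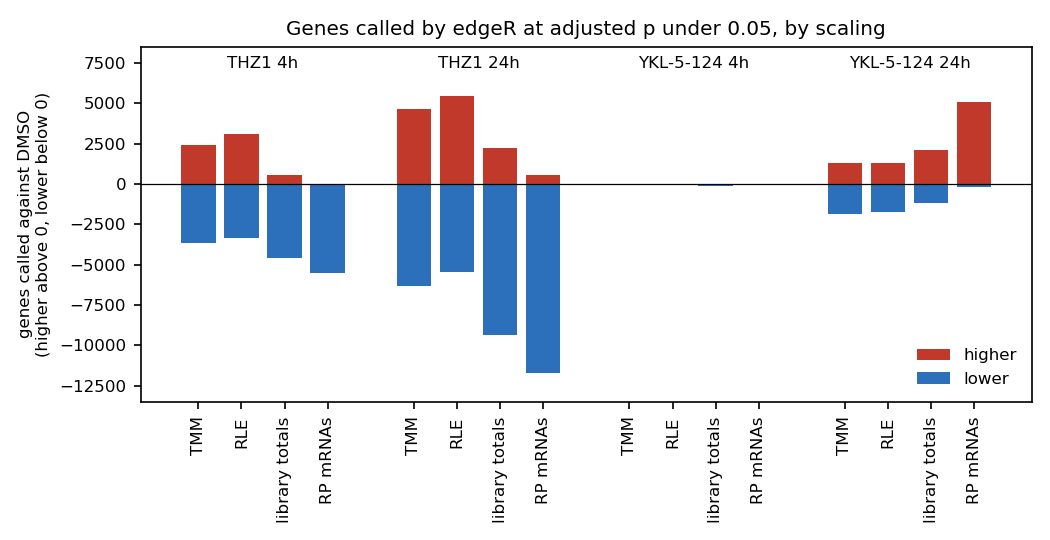
Number of genes called by edgeR at the adjusted p threshold of 0.05, higher (above 0) and lower (below 0) than DMSO, for each compound and time under TMM, RLE factors, library totals and ribosomal protein (RP) mRNAs as the reference. The split for THZ1 24 h was 5449 higher and 5457 lower under RLE factors, 4657 and 6352 under TMM, and 572 and 11708 against RP mRNAs. The bars of YKL-5-124 4 h (8 and 68 under TMM) are too short to see.

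The libraries of a group also differed along an axis tied to transcript length. MKI67, a marker of proliferating cells chosen here after its values were seen, ranged from 22.3 to 454 CPM over the 3 DMSO libraries and from 19.1 to 408 CPM over the 3 YKL-5-124 24 h libraries. Of the 14461 genes, it had the largest weight in its own direction on the main axis of variation within groups, which held 37.4% of that variance. Weights in the other direction were not compared with it. MKI67 passed the test in none of the 9 comparisons. Against DMSO its log2 fold changes (with SE) were −0.21 ± 1.56 for THZ1 4 h, −2.75 ± 1.62 for THZ1 24 h, −0.53 ± 1.56 for YKL-5-124 4 h and −0.17 ± 1.56 for YKL-5-124 24 h.

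**Figure D2:**
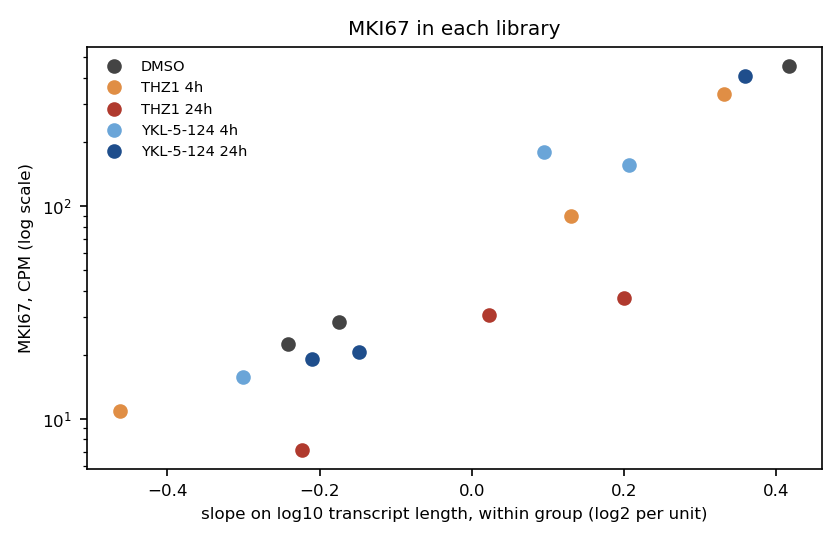
MKI67 level of each of the 15 libraries (CPM, log axis) against the slope of the library's log2 deviations from its group mean on log10 transcript length; each point is 1 library, coloured by group. Over the 3 DMSO libraries the level ran from 22.3 CPM at a slope of −0.24 to 454 CPM at a slope of 0.42.

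After 4 h of THZ1, transcripts of many inducible regulators fell. DUSP1, a phosphatase that inactivates MAP kinases (GRCh38 chromosome 5, 172768090 to 172771195), fell from 60.8 ± 14.1 CPM in DMSO to 2.06 ± 0.296 CPM (mean ± SD, n = 3 libraries each). Its log2 fold change was −4.88 ± 0.23 (SE; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 8.61e-10), and the 3 treated libraries lay below the 3 DMSO libraries. MCL1, an anti-apoptotic member of the BCL2 family (chromosome 1, 150574551 to 150579738), fell from 445 ± 32.0 to 78.6 ± 14.0 CPM. The largest falls by log2 fold change (with SE, as in the rest of the text) were CHAC1, a glutathione-degrading enzyme (−5.32 ± 0.60), HPS6, a subunit of a lysosome biogenesis complex (−4.93 ± 0.30), DUSP1 and the zinc finger gene ZNF627 (−4.88 ± 0.44). Without THZ1 4 h replicate 1, CHAC1 was at −7.27, HPS6 at −5.65 and ZNF627 at −6.15. All largest changes are among protein-coding genes with a mean of at least 5 CPM over all 15 libraries, and some less abundant genes rose more. Within that limit the rises at THZ1 4 h were smaller than the falls, the largest being the immediate-early gene ARC, which the fixed list does not hold (2.01 ± 0.60; not called against ribosomal protein mRNAs), at 0.133 ± 0.121 CPM in DMSO and 0.578 ± 0.259 CPM after THZ1. It reached the 5 CPM only through the THZ1 24 h libraries (35.1 to 47.0 CPM). Its change was 3.03 without DMSO replicate 2. Others were the TRAIL decoy receptor TNFRSF10D (1.46 ± 0.18) and the stress-induced SESN1 (1.35 ± 0.22).

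Of the 32 immediate-early and short-lived transcripts tested, 0 rose and 27 fell (0 and 27 adjusted over the list alone), with a median of −2.33. The list was lower than other genes (camera with Benjamini-Hochberg adjustment, adjusted p = 4.76e-20; adjusted p = 0.00609 with an estimated correlation). Its largest falls were DUSP1 and the transcription factor KLF2, which had 7 counts over the 3 THZ1 libraries (6 of them in replicate 2), 0.0338 of its DMSO level (95% counting interval 0.0135 to 0.0707). Of 21 genes of ERK pathway output, 0 rose and 13 fell (0 and 13 adjusted over the list alone), at a median of −1.04 (camera with Benjamini-Hochberg adjustment, adjusted p = 1.09e-09; adjusted p = 0.0196 with an estimated correlation). They included the ERK phosphatases DUSP5 (−4.21 ± 0.12) and DUSP6 (−3.63 ± 0.12). Among 26 genes of ATF4 and the unfolded protein response, 7 rose and 12 fell (8 and 13 adjusted over the list alone), at a median of −0.47. CHAC1 and the mTOR inhibitor DDIT4 (−3.89 ± 0.43) fell, while the endoplasmic reticulum chaperone HSP90B1 rose (0.86 ± 0.13; not called against ribosomal protein mRNAs). Camera with Benjamini-Hochberg adjustment called this list lower (adjusted p = 0.000689), and the call was lost at adjusted p = 0.277 with an estimated correlation. Of 13 mitochondrially encoded mRNAs, 9 rose and 0 fell (9 and 0 adjusted over the list alone), at a median of 0.82, against 5 and 0 under library totals and 0 and 0 against ribosomal protein mRNAs. That call (camera with Benjamini-Hochberg adjustment, adjusted p = 0.00071) was lost at adjusted p = 0.456 with an estimated correlation, and the list median lay above all DMSO libraries in 2 of 3 THZ1 libraries.

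Other lists held strong falls at 4 h without passing the set test as a whole. In homologous recombination and Fanconi genes 6 rose and 13 fell of 33 (9 and 13 adjusted over the list alone), with FANCF (−3.72 ± 0.20), of the Fanconi core complex, and PALB2, the partner of BRCA2 (−3.33 ± 0.23), among the falls. The ATR checkpoint list had 3 rises and 11 falls of 26 (4 and 13 adjusted over the list alone), including the ATR activator ETAA1 (−4.39 ± 0.22) and the kinase WEE1 (−3.78 ± 0.19). The BCL2 family list had 1 rise and 11 falls of 24 (1 and 11 adjusted over the list alone), MCL1 (−2.50 ± 0.12) and the pro-apoptotic BBC3 (−1.93 ± 0.34; −2.56 without THZ1 4 h replicate 1) among them. NF-kB targets gave 1 rise and 10 falls of 21 (1 and 10 adjusted over the list alone), with the NF-kB inhibitors NFKBIE (−3.26 ± 0.34; −4.14 without THZ1 4 h replicate 1) and NFKBIA (−2.88 ± 0.22) lower. In the p53 target list 4 rose and 8 fell of 25 (4 and 8 adjusted over the list alone). PLK2 (−3.92 ± 0.19) and BTG2 (−3.29 ± 0.26) fell and SESN1 rose, while the median was 0.02 and the mean −0.41. Among cyclins, CDK inhibitors and RB family genes 5 rose and 6 fell of 22 (5 and 6 adjusted over the list alone; 6 and 5 by DESeq2), with the CDK inhibitor CDKN1B at −2.69 ± 0.15. The G1/S list had 11 rises and 15 falls of 43 (12 and 16 adjusted over the list alone; 0 and 22 against ribosomal protein mRNAs), with the phosphatase CDC25A (−2.59 ± 0.13) and the transcription factor E2F8 (−2.50 ± 0.24) lower.

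In total 2441 genes were higher and 3632 lower in THZ1 4 h than in DMSO, of which 107 and 2453 differed at least 2-fold. With each library's transcript length slope as a covariate, chosen after seeing the data and taking up spread within groups only, 4173 were higher. Under library totals the split was 588 and 4619, and against ribosomal protein mRNAs it was 29 and 5502. It was nearly even under RLE factors, at 3127 and 3354, and by DESeq2 over the same genes, at 3227 and 3369. Upper-quartile factors gave 2690 and 3573. CDK7 fell by 0.43 on the log2 scale, but that call ended without DMSO replicate 1, DMSO replicate 3, THZ1 4 h replicate 2 or THZ1 4 h replicate 3 (edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.0977 to 0.11) and under RLE factors (edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.0848). It also ended by DESeq2 (−0.35) and with only the groups compared in the fit (−0.43). CDK12 (−0.49 ± 0.18) and CDK13 (−1.02 ± 0.30) fell as well. The CDK13 call ended without DMSO replicate 2 (−0.68) or THZ1 4 h replicate 1 (−0.80). That of CDK12 ended without DMSO replicate 2 (−0.30), DMSO replicate 3 (−0.54), THZ1 4 h replicate 1 (−0.34) or THZ1 4 h replicate 3 (−0.47). It ended too under RLE (−0.40) or upper-quartile factors (−0.47), by DESeq2 (−0.40) and with only the groups compared in the fit (−0.50).

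After 24 h of THZ1, genes of G2/M and mitosis were lower as a group, CDK7 was lower, and the immediate-early genes EGR1 and FOS were higher. CDC6, which loads the replicative helicase (GRCh38 chromosome 17, 40287633 to 40304657), fell from 72.0 ± 4.88 CPM in DMSO to 2.24 ± 0.190 CPM (mean ± SD, n = 3 each), a log2 fold change of −5.00 ± 0.16 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 2e-12; lower in 3 of 3 libraries). TTK, a mitotic checkpoint kinase, fell from 117 ± 12.5 to 4.36 ± 0.482 CPM. CDK7 itself (chromosome 5, 69234795 to 69277430) fell from 62.9 ± 7.44 to 5.02 ± 0.412 CPM. EGR1, an immediate-early transcription factor (chromosome 5, 138465490 to 138469315), rose from 1.45 ± 0.448 to 389 ± 170.2 CPM, and FOS, a subunit of AP-1, from 1.69 ± 0.818 to 359 ± 33.1 CPM.

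The largest rises were MROH8 (8.77 ± 0.41), PLCB1, a phospholipase C (8.45 ± 0.49; chromosome 20, 8114453 to 8968360), ARC, a synaptic immediate-early gene (8.14 ± 0.54; 9.14 without DMSO replicate 2), and EGR1 (8.06 ± 0.39). MROH8 is uncertain, because it overlaps RPN2 on the opposite strand and the use of strand in the counting is not given in the sources used here. The largest falls were PAFAH2, an acetylhydrolase of platelet-activating factor, TMEM121, the planar polarity gene VANGL1 (−5.66 ± 0.23) and the inflammasome gene NLRP3 (−5.46 ± 0.41). PAFAH2 had 3 counts over the 3 THZ1 libraries (2 of them in replicate 2), 0.0112 of its DMSO level (95% counting interval 0.00231 to 0.0329), and TMEM121 had 4 (0.0156, interval 0.00425 to 0.0402).

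Of 40 genes of G2/M and mitosis, 2 rose and 35 fell (2 and 35 adjusted over the list alone), at a median of −2.60. The list was lower than other genes (camera with Benjamini-Hochberg adjustment, adjusted p = 6.45e-15; adjusted p = 0.000156 with an estimated correlation), with the chromosomal passenger gene CDCA8 at −4.59 ± 0.13. In ribosome biogenesis 5 rose and 20 fell of 31 (5 and 20 adjusted over the list alone), at a median of −1.23 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.000416; adjusted p = 0.0432 with an estimated correlation), BYSL (−5.17 ± 0.25) and the nucleolar GTPase GNL3 (−4.79 ± 0.15; uncertain, since it overlaps PBRM1) falling most. For the G1/S list, 10 rose and 29 fell of 43 (10 and 29 adjusted over the list alone) at a median of −1.54. For homologous recombination and Fanconi genes it was 5 and 22 of 33 (5 and 22 adjusted over the list alone), with BRCA2 at −4.03 ± 0.30 and the exonuclease EXO1 at −3.84 ± 0.25. The ATR checkpoint list gave 4 and 19 of 26 (5 and 19 adjusted over the list alone). The Pol II kinase and general transcription list gave 3 and 21 of 31 (3 and 21 adjusted over the list alone) at a median of −1.01, with CDK7 (−3.64 ± 0.18), CDK12 (−3.05 ± 0.20) and CDK13 (−1.92 ± 0.32) all lower. The camera calls of these 4 lists, with Benjamini-Hochberg adjustment, had adjusted p = 0.00292, 0.00738, 0.0455 and 0.0122, and were lost at adjusted p = 0.263, 0.173, 0.37 and 0.0641 with an estimated correlation.

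Among immediate-early and short-lived transcripts 20 rose and 4 fell of 32 (20 and 4 adjusted over the list alone) at a median of 1.05, but 12 and 12 under library totals and 10 and 20 against ribosomal protein mRNAs. EGR1 and FOS (7.74 ± 0.41) stayed higher under each scaling. Of 23 mesenchymal and EMT genes, 18 rose and 3 fell (18 and 3 adjusted over the list alone), at 8 and 7 under library totals and 0 and 9 against ribosomal protein mRNAs. Of 14 replication-dependent histones, 9 rose and 1 fell (9 and 1 adjusted over the list alone), at 6 and 2 under library totals and 2 and 7 against ribosomal protein mRNAs. Histone genes are near-identical copies, so their single values are uncertain. All 13 mitochondrially encoded mRNAs rose (13 adjusted over the list alone) at a median of 2.77, as under library totals, whereas 2 rose against ribosomal protein mRNAs. The camera calls of these 4 lists, with Benjamini-Hochberg adjustment, had adjusted p = 8.83e-06, 0.0179, 0.012 and 2.15e-06, and were lost at adjusted p = 0.157, 0.486, 0.515 and 0.316 with an estimated correlation.

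Another 10 lists, from cyclins to hypoxia, did not pass the set test at THZ1 24 h, and their members went both ways. Cyclins, CDK inhibitors and RB family genes gave 9 rises and 10 falls of 22 (9 and 10 adjusted over the list alone; 11 and 7 under RLE factors). The CDK inhibitor gene CDKN2A (2.88 ± 0.19) rose and the transcription factor E2F3 (−2.63 ± 0.18) fell. NF-kB targets gave 11 and 8 of 21 (11 and 8 adjusted over the list alone; 4 and 10 under library totals and 3 and 15 against ribosomal protein mRNAs), with the chemokine CXCL3 higher (6.11 ± 0.44) and the cytokine IL1A lower (−3.29 ± 0.77). ERK pathway output gave 5 and 11 of 21 (5 and 11 adjusted over the list alone), from the neuropeptide precursor VGF (5.38 ± 0.41) to the phosphatase DUSP4 (−4.94 ± 0.42). The BCL2 family gave 4 and 15 of 24 (4 and 15 adjusted over the list alone), with the pore-forming BAK1 (−4.06 ± 0.20) lower. For p53 targets it was 6 and 16 of 25 (7 and 16 adjusted over the list alone), PHLDA3 at −3.17 ± 0.31. For interferon-stimulated genes it was 5 and 16 of 29 (5 and 15 adjusted over the list alone), IFIT5 at −5.17 ± 0.37. The ATF4 list gave 5 and 17 of 26 (5 and 17 adjusted over the list alone), with the lipoprotein receptor VLDLR at −2.98 ± 0.32. Heat shock genes gave 6 and 10 of 20 (6 and 10 adjusted over the list alone), with the chaperone HSPA8 lower (−4.01 ± 0.18) and HSPB1 higher (2.99 ± 0.17). Cholesterol synthesis gave 8 and 10 of 24 (8 and 10 adjusted over the list alone; 12 and 10 under RLE factors) with a median of 0.09 and a mean of −0.43, and SQLE, squalene epoxidase, at −3.86 ± 0.12. Hypoxia and glycolysis gave 12 and 9 of 22 (12 and 9 adjusted over the list alone; 9 and 11 under library totals and 2 and 16 against ribosomal protein mRNAs), with LDHA lower (−3.30 ± 0.10) and ALDOC higher (2.99 ± 0.27).

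Epithelial and pancreatic ductal genes gave 6 rises and 6 falls of 13 at THZ1 24 h (6 and 6 adjusted over the list alone; 4 and 7 under library totals and 6 and 4 under RLE factors), with a median of −0.60 and a mean of 0.02. Neither this list nor the stromal, endothelial and immune list passed the set test, and the acinar, islet and liver list had no set test. E-cadherin, CDH1, rose (4.47 ± 0.41) and the transcription factor GATA4 fell (−3.66 ± 0.32). Among markers of other cell types, 3 of 6 stromal, endothelial and immune genes rose and 0 fell (3 and 0 adjusted over the list alone), 3 and 1 under library totals and 0 and 2 against ribosomal protein mRNAs; COL1A1, a fibrillar collagen, was among them (3.51 ± 0.79; 2.775 without THZ1 24 h replicate 2). The 1 tested member of the acinar, islet and liver list, SERPINA1, rose (1.98 ± 0.43; 1 adjusted over the list alone), but it was not called under library totals (0.86) or against ribosomal protein mRNAs (−0.16). For all lists called by camera in this comparison, the list median of each THZ1 library lay beyond those of the 3 DMSO libraries.

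**Figure D3:**
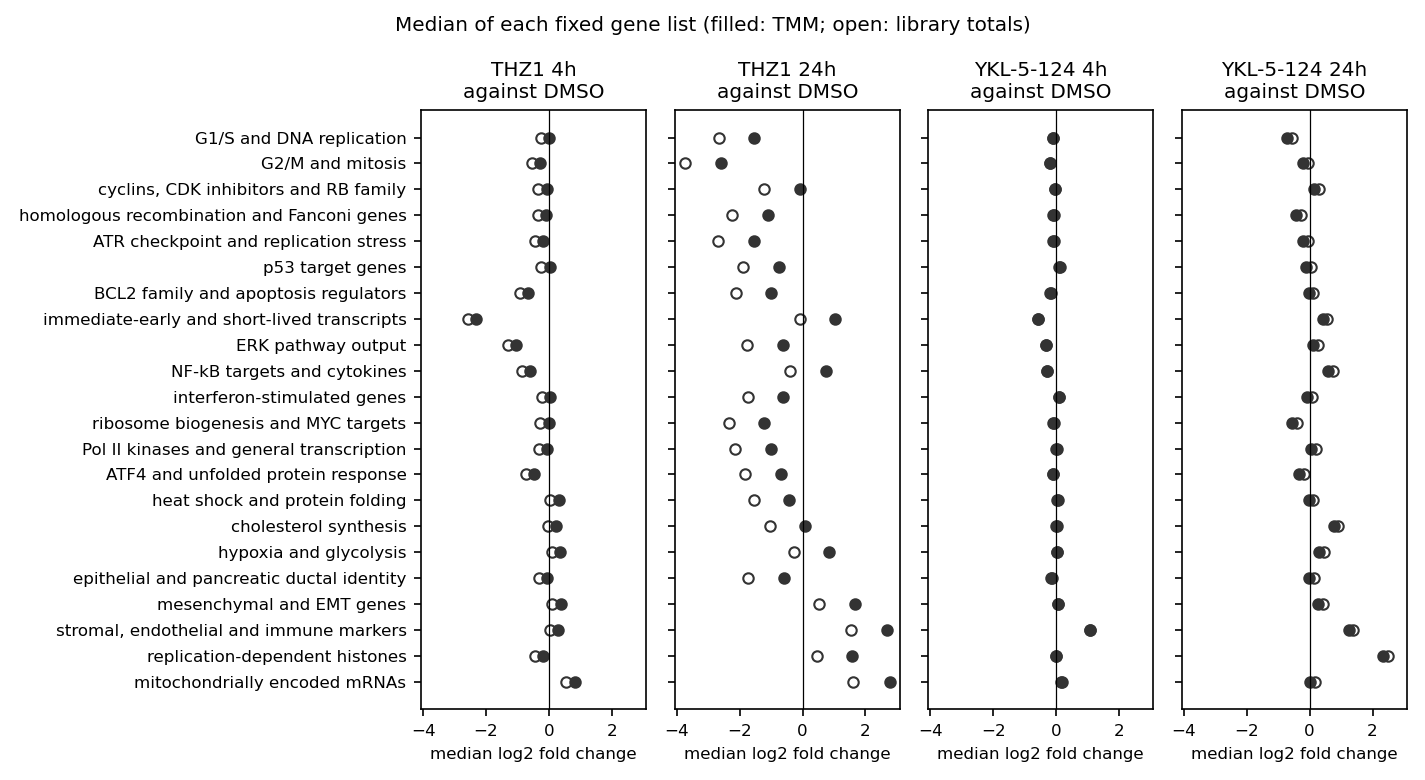
Median log2 fold change against DMSO of each gene list with at least 5 members tested, in 4 panels for the compounds and times (filled circles, TMM; open circles, library totals). At THZ1 24 h the immediate-early median was 1.05 under TMM and −0.09 under library totals, while that of G2/M and mitosis was −2.60 and −3.74.

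After 4 h of YKL-5-124, ADM, which encodes adrenomedullin (GRCh38 chromosome 11, 10304680 to 10307397), fell from 307 ± 32.5 to 105 ± 16.2 CPM (mean ± SD, n = 3 each), a log2 fold change of −1.55 ± 0.15 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.000172; lower in 3 of 3 libraries). The kinase PLK2 fell as well (−1.34 ± 0.18), and the endothelial early-response gene APOLD1 (1.62 ± 0.23) and TNFRSF10D (1.22 ± 0.18) rose. These calls held without each library in turn. In total 8 genes were higher and 68 lower, 5 and 29 of them at least 2-fold, while 1408 genes had an unadjusted p under 0.05. DESeq2 called 69 and 279, and with the transcript length slope as a covariate, which takes up spread within groups only, 404 and 863 were called. With no filter beyond 1 count it was 39 and 151, and with only the groups compared in the fit 1 and 16. The higher and lower counts were 3 and 30 without DMSO replicate 1, 2 and 22 without DMSO replicate 3, 2 and 12 without YKL-5-124 4 h replicate 2, and 3 and 23 without YKL-5-124 4 h replicate 3.

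Of the 32 immediate-early and short-lived transcripts, 0 rose and 6 fell at YKL-5-124 4 h (0 and 17 adjusted over the list alone), at a median of −0.56. The list was lower than other genes (camera with Benjamini-Hochberg adjustment, adjusted p = 1.04e-19; adjusted p = 0.00637 with an estimated correlation), and its largest fall was the kinase SGK1 (−1.20 ± 0.17), a call that ended without YKL-5-124 4 h replicate 2 (edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.0501). The G2/M list held 0 rises and 1 fall of 40 (0 and 2 adjusted over the list alone), at a median of −0.18 (camera with Benjamini-Hochberg adjustment, adjusted p = 3.53e-05; adjusted p = 0.00609 with an estimated correlation). That fall was the centromeric histone CENPA (−0.70 ± 0.11), which was not called without YKL-5-124 4 h replicate 2 (edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.0654). ERK pathway output gave 0 and 1 of 21 (0 and 7 adjusted over the list alone), ribosome biogenesis 0 and 1 of 31 (0 and 2 adjusted over the list alone) and NF-kB targets 0 and 0 of 21 (0 and 1 adjusted over the list alone), at medians of −0.30, −0.08 and −0.28. Their camera calls, with Benjamini-Hochberg adjustment, had adjusted p = 3.53e-05, 0.0143 and 0.0249, and were lost at adjusted p = 0.103, 0.159 and 0.157 with an estimated correlation. The other lists did not pass the set test. CDK7 (−0.20 ± 0.15), CDK12 (−0.16 ± 0.18) and CDK13 (−0.01 ± 0.29) did not pass the test, with 95% intervals of −0.52 to 0.12, −0.54 to 0.22 and −0.63 to 0.61.

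After 24 h of YKL-5-124, genes of DNA replication and ribosome biogenesis were lower, and histone and cholesterol synthesis genes were higher. Against ribosomal protein mRNAs the median of ribosome biogenesis was 0.02, but those mRNAs themselves took 7.92% of the counts there and 10.7% in DMSO. CDC45, a subunit of the replicative helicase, fell from 45.1 ± 7.91 CPM in DMSO to 15.6 ± 0.676 CPM (mean ± SD, n = 3 each), a log2 fold change of −1.53 ± 0.15 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 1.12e-05; lower in 3 of 3 libraries). HMGCS1, which makes HMG-CoA for cholesterol synthesis (GRCh38 chromosome 5, 43289395 to 43313512), rose from 60.1 ± 3.75 to 224 ± 30.6 CPM. CDKN1A, the CDK inhibitor p21, rose from 42.1 ± 10.2 to 155 ± 14.3 CPM. The largest rises were the histone genes HIST1H2BJ (4.20 ± 0.33) and HIST1H2AG (3.70 ± 0.27), the receptor FGFR3 (3.38 ± 0.23) and ARC (2.98 ± 0.56; 4.00 without DMSO replicate 2). Here too, ARC reached the mean of 5 CPM only through the THZ1 24 h libraries. The largest falls were the cytokine receptor IL31RA (−2.01 ± 0.27), OSGIN1 (−2.01 ± 0.24), the tRNA-modifying enzyme ALKBH8 (−1.92 ± 0.14) and the sphingosine receptor S1PR1 (−1.90 ± 0.19).

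In the G1/S list 1 gene rose and 32 fell of 43 (1 and 36 adjusted over the list alone), at a median of −0.71 (camera with Benjamini-Hochberg adjustment, adjusted p = 1.81e-19; adjusted p = 0.00402 with an estimated correlation). Against ribosomal protein mRNAs, 3 rose and 7 fell. In ribosome biogenesis 0 rose and 20 fell of 31 (0 and 23 adjusted over the list alone), at a median of −0.56, with the uncertain GNL3 at −1.05 ± 0.13; against ribosomal protein mRNAs 3 fell, at a median of 0.02. Homologous recombination and Fanconi genes gave 0 rises and 13 falls of 33 (0 and 21 adjusted over the list alone), with FANCE at −1.25 ± 0.19, against 3 and 1 with ribosomal protein mRNAs as the reference. Camera with Benjamini-Hochberg adjustment called these last lists lower (adjusted p = 6.93e-12 and 5.89e-05; adjusted p = 0.00276 and 0.0339 with an estimated correlation). Of 24 cholesterol synthesis genes 17 rose and 0 fell (19 and 0 adjusted over the list alone), at a median of 0.77, with the isomerase IDI1 at 1.49 ± 0.20. Of 14 replication-dependent histones 10 rose and 1 fell (10 and 1 adjusted over the list alone), at a median of 2.33, HIST1H2AC among them (2.86 ± 0.42). NF-kB targets gave 8 rises and 0 falls of 21 (9 and 0 adjusted over the list alone), at a median of 0.60, and TNF rose (3.53 ± 0.74; 5.32 without DMSO replicate 1) to 1.84 ± 0.922 CPM. Camera with Benjamini-Hochberg adjustment called these 3 lists higher (adjusted p = 8.42e-18, 8.42e-18 and 3.69e-05; adjusted p = 0.0339, 0.0368 and 0.0225 with an estimated correlation).

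The immediate-early list gave 12 rises and 2 falls of 32 at YKL-5-124 24 h (15 and 2 adjusted over the list alone), with the AP-1 genes JUNB (2.38 ± 0.22) and FOS (2.05 ± 0.42) higher. Hypoxia and glycolysis gave 10 and 5 of 22 (11 and 5 adjusted over the list alone), with the regulator of glycolysis PFKFB4 (1.82 ± 0.25) and NDRG1 (1.78 ± 0.16) higher. The ATR checkpoint list gave 1 and 9 of 26 (1 and 11 adjusted over the list alone), with the fork protection gene TIPIN at −1.64 ± 0.22; against ribosomal protein mRNAs the list turned to 8 and 1. The ATF4 list gave 0 and 10 of 26 (0 and 13 adjusted over the list alone), CHAC1 at −1.88 ± 0.40, and turned to 5 and 2 against ribosomal protein mRNAs. The camera calls of these 4 lists, with Benjamini-Hochberg adjustment, had adjusted p = 3.53e-05, 0.000356, 0.00334 and 0.0292, and were lost at adjusted p = 0.173, 0.306, 0.185 and 0.446 with an estimated correlation. G2/M and mitosis gave 0 rises and 9 falls of 40 (0 and 9 adjusted over the list alone) and did not pass the set test. The list gave 4 and 5 under library totals and turned to 9 and 0 against ribosomal protein mRNAs. Cyclins, CDK inhibitors and RB family genes gave 8 and 7 of 22 (9 and 9 adjusted over the list alone), with CDKN1C (2.17 ± 0.25) and CDKN1A (1.88 ± 0.20) higher. Of p53 targets 5 rose and 6 fell of 25 (6 and 8 adjusted over the list alone; 6 and 5 under library totals and 13 and 1 against ribosomal protein mRNAs), TP53I3 at 1.15 ± 0.19 and the repair gene DDB2 at −1.05 ± 0.18. Among heat shock genes 3 rose and 2 fell of 20 (3 and 2 adjusted over the list alone), HSPA1A at 1.87 ± 0.23. Mesenchymal genes gave 3 and 2 of 23 (3 and 2 adjusted over the list alone). Of 13 mitochondrially encoded mRNAs 0 rose and 0 fell (0 and 0 adjusted over the list alone).

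In total 1293 genes were higher and 1847 lower at YKL-5-124 24 h, 591 and 355 of them at least 2-fold. With the transcript length slope as a covariate they were 2663 and 3642. The split turned to 1748 and 1381 under upper-quartile factors, 2096 and 1186 under library totals and 5074 and 196 against ribosomal protein mRNAs. Without DMSO replicate 3 the counts were 764 and 1173, and without DMSO replicate 1 the lower count was 1214. CDK7 (0.05 ± 0.15), CDK12 (0.05 ± 0.18) and CDK13 (0.15 ± 0.29) did not pass the test, with 95% intervals of −0.27 to 0.37, −0.33 to 0.43 and −0.47 to 0.77; against ribosomal protein mRNAs CDK7 was called higher (0.63).

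The compounds were compared directly at the same dose and time. At 4 h, DUSP1 was lower with THZ1 than with YKL-5-124 by a log2 difference of −3.73 ± 0.23 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 1.11e-08; lower in 3 of 3 libraries), as were MCL1 (−2.27 ± 0.12), FANCF (−3.39 ± 0.20), ETAA1 (−3.72 ± 0.22) and ADM (−3.07 ± 0.15). The largest differences were ZNF627 (−5.21 ± 0.44), HPS6 (−5.00 ± 0.30), MOCS3, a gene of molybdenum cofactor synthesis (−4.75 ± 0.29), and CHAC1 (−4.71 ± 0.60) on the lower side and, among others, SESN1 (1.16 ± 0.22) and the stress-response gene IER3 (1.06 ± 0.25) on the higher. Without THZ1 4 h replicate 1, ZNF627 was at −6.49, HPS6 at −5.73 and CHAC1 at −6.69. Of the immediate-early list 0 were higher and 26 lower with THZ1 of 32 (0 and 26 adjusted over the list alone), and of ERK pathway output 1 and 13 of 21 (1 and 14 adjusted over the list alone). Camera with Benjamini-Hochberg adjustment called both lower (adjusted p = 6.45e-15 and 3.53e-08; adjusted p = 0.0134 and 0.0339 with an estimated correlation), at medians of −1.45 and −0.77. CDK13 was lower with THZ1 (−1.01 ± 0.30), a call lost without THZ1 4 h replicate 1 (−0.79), THZ1 4 h replicate 3 (−1.09), YKL-5-124 4 h replicate 2 (−0.84) or YKL-5-124 4 h replicate 3 (−0.91). No difference passed the test for CDK7 (−0.23 ± 0.15, 95% interval −0.55 to 0.09), CDK12 (−0.32 ± 0.18, −0.71 to 0.06) or TNFRSF10D (0.24 ± 0.18, −0.14 to 0.61), which rose with both compounds. CDK7 was called lower under library totals (−0.48), against ribosomal protein mRNAs (−0.67) and without THZ1 4 h replicate 1 (−0.39), and CDK12 without THZ1 4 h replicate 2 (−0.53). In total 1665 genes were higher and 3162 lower with THZ1 than with YKL-5-124 at 4 h, 202 and 4174 under library totals, 25 and 4444 against ribosomal protein mRNAs, 2536 and 2884 under RLE factors and 2722 and 2951 by DESeq2 over the same genes. The higher count was 3666 with the transcript length slope as a covariate and 1032 with only the groups compared in the fit. Library totals moved the median of all genes by −0.24 and ribosomal protein mRNAs by −0.42. Without THZ1 4 h replicate 3 the higher count was 999, and without YKL-5-124 4 h replicate 3 it was 1011.

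At 24 h, CDC6 (−4.49 ± 0.16), TTK (−4.44 ± 0.17) and CDK7 (−3.69 ± 0.18) were lower with THZ1 than with YKL-5-124, as were CDK12 (−3.10 ± 0.20) and CDK13 (−2.07 ± 0.32). SQLE (−4.58 ± 0.12) and HMGCS1 (−3.36 ± 0.14) of cholesterol synthesis and CDKN1A (−2.60 ± 0.21) were lower with THZ1 as well, while EGR1 (7.19 ± 0.36) and FOS (5.70 ± 0.35) were higher. Of 24 cholesterol synthesis genes 7 were higher and 13 lower (7 and 13 adjusted over the list alone). Camera with Benjamini-Hochberg adjustment called that list lower (adjusted p = 0.0292), a call lost at adjusted p = 0.576 with an estimated correlation. PLCB1 (8.82 ± 0.51), MROH8 (8.66 ± 0.40) and the Fc receptor-like gene FCRLB (7.51 ± 0.33) were the largest on the higher side, and PAFAH2, VANGL1 (−5.77 ± 0.23), TMEM121 and RAB40C on the lower. Of the G2/M list 2 were higher and 34 lower of 40 (2 and 34 adjusted over the list alone), and of the Pol II list 2 and 21 of 31 (2 and 21 adjusted over the list alone). Camera with Benjamini-Hochberg adjustment called both lower (adjusted p = 2.48e-13 and 0.00275; adjusted p = 2e-04 and 0.0339 with an estimated correlation), at medians of −2.53 and −1.10. The histone gene HIST1H2AG rose with both compounds, and its difference of 0.51 ± 0.25 did not pass the test (95% interval −0.04 to 1.05). In total 4593 genes were higher and 6366 lower with THZ1 than with YKL-5-124 at 24 h, 1992 and 9918 under library totals and 275 and 12942 against ribosomal protein mRNAs, which moved the median of all genes by −1.27 and −2.77. RLE factors moved it by 0.32, upper-quartile factors by 0.30 and DESeq2 by 0.28.

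Within a compound, 24 h was compared with 4 h. With THZ1, MROH8 (9.04 ± 0.46), PLCB1 (8.47 ± 0.51) and FCRLB (8.32 ± 0.42) rose most, and PCNA, the replication clamp (−4.75 ± 0.14), PAFAH2 and the histone chaperone NASP (−4.59 ± 0.14) fell most. Without THZ1 4 h replicate 1, PLCB1 was at 9.95 and FCRLB at 9.19. Of the immediate-early list 30 rose and 0 fell from 4 h to 24 h of 32 (30 and 0 adjusted over the list alone), at a median of 3.78 (camera with Benjamini-Hochberg adjustment, adjusted p = 3.55e-27; adjusted p = 0.00316 with an estimated correlation), 26 and 1 under library totals and 25 and 1 against ribosomal protein mRNAs. DUSP1 rose (3.99 ± 0.23). With YKL-5-124, HIST1H2BJ (4.14 ± 0.33), the NOTCH target HES1 (3.49 ± 0.58) and HIST1H2AG (3.43 ± 0.27) rose most, and CPSF6, a 3′ end processing factor (−1.94 ± 0.09), DHRS11 (−1.92 ± 0.14) and IL31RA (−1.92 ± 0.27) fell most. There the immediate-early list gave 24 rises and 0 falls of 32 (25 and 0 adjusted over the list alone), at a median of 0.91 (camera with Benjamini-Hochberg adjustment, adjusted p = 9.28e-20; adjusted p = 0.00637 with an estimated correlation). In all, with THZ1 4532 genes were higher and 5159 lower at 24 h than at 4 h. The split was 5744 and 3919 under upper-quartile factors, 2284 and 8163 under library totals and 749 and 10369 against ribosomal protein mRNAs, with the median of all genes moved by 0.37, −0.86 and −1.65 (RLE factors 0.24, DESeq2 0.20). With YKL-5-124 it was 1334 and 1727, 2752 and 3509 with the transcript length slope as a covariate, 2288 and 1046 under library totals and 6742 and 127 against ribosomal protein mRNAs (median moved by 0.16 and 0.67). Without YKL-5-124 4 h replicate 3 the higher count was 871, and without YKL-5-124 24 h replicate 2 it was 879.

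The change from 4 h to 24 h was compared between the compounds in an interaction test, in which DMSO cancels. Of the G2/M list 1 gene changed more upwards with THZ1 and 35 more downwards of 40 (1 and 35 adjusted over the list alone), at a median difference of −2.33, TTK among them. Of the immediate-early list 25 changed more upwards and 1 more downwards of 32 (26 and 1 adjusted over the list alone), at a median of 2.61, and of the Pol II list 3 and 15 of 31 (3 and 16 adjusted over the list alone), at a median of −0.68. Camera with Benjamini-Hochberg adjustment called these lists (adjusted p = 1.45e-18, 4.66e-18 and 0.00468; adjusted p = 7.77e-05, 0.00687 and 0.0348 with an estimated correlation). The gene counts were 3838 and 4477 under TMM, 4700 and 3534 under upper-quartile factors, 1556 and 7902 under library totals and 197 and 11345 against ribosomal protein mRNAs. The median of all genes moved by 0.31, −1.03 and −2.33 in the last 3, by 0.23 under RLE factors and by 0.19 in DESeq2.

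Calls against DMSO were also compared between compounds and times. Among the 14461 genes, 62 were lower and 3 higher with both compounds at 4 h, where independent lists of these sizes share 17.1 and 1.35, and 3 went in opposite directions. At 24 h, 1011 were lower and 616 higher with both, against 811 and 416 for independent lists, and 936 went in opposite directions. The opposite calls were not set beside a value for independent lists, and all overlaps were counted under TMM only. For THZ1 at 4 h and 24 h, 3061 were lower and 1961 higher at both, against 1595 and 786, and for YKL-5-124 41 and 3, against 8.69 and 0.715. Across genes, which are not independent replicates, log2 fold changes of the compounds had a Pearson correlation of 0.418 at 4 h and 0.227 at 24 h, where 20 simulations of unchanged groups sharing these controls averaged 0.500 and 0.493. The covariance was 0.185 at 4 h and 0.331 at 24 h, against simulated covariances of 0.0486 and 0.0484. For THZ1 4 h with 24 h the correlation was 0.546 and the covariance 1.19, against 0.493 and 0.0484 simulated, and for YKL-5-124 they were 0.386 and 0.114, against 0.499 and 0.0485. The covariances exceeded the simulated ones by 0.136 and 0.283 for the compounds at 4 h and 24 h, 1.14 for THZ1 and 0.0658 for YKL-5-124. The simulations shared on average 0 to 0.05 calls, but they hold no real effects. They also drew genes independently, so covariance from variation that genes share within groups, the DMSO libraries included, is not covered. The excess covariances are therefore not shown to come from treatment alone. The simulated correlations follow from equal group sizes and shared controls, so setting the real ones beside them decides nothing. Since 3 controls cannot be divided into groups of at least 2, the overlap of calls was not repeated with separate DMSO libraries.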

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

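The tests of the scaling in this part were chosen only after the result was seen, and the splits of the libraries were planned. The change from 4 h to 24 h differed between THZ1 and YKL-5-124 by the interaction test for 3838 genes in the higher and 4477 in the lower direction. The largest differences on the higher side (log2) were MROH8, which is uncertain because it overlaps RPN2 (9.07), the phospholipase C gene PLCB1 (8.72) and FCRLB (8.05). Without THZ1 4 h replicate 1, the latter were at 10.2 and 8.92. Those on the lower side were NLRP2 (−4.93), VANGL1 (−4.73) and the cholesterol synthesis gene SQLE (−4.50). Of 60 splits of the compound labels within times, taken from 200 possible, 5 called at least the real 8315 genes, the real one included, and the highest other called 9200, so chance was not excluded by this count. The 4 others as large kept or exchanged all compound labels at 24 h, and the splits that mixed the labels at 24 h called at most 222 genes. Mixing turns the difference between compounds into spread within groups, so those low counts do not test chance.

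The 8 comparisons between groups of 3 libraries allow 10 splits each, too few for a share under 0.05. For YKL-5-124 4 h against DMSO, 2 of the 10 splits called as many genes as the real 76. The other called 555 and set DMSO replicates 1 and 3 and YKL-5-124 4 h replicate 1 against the rest, which parts the libraries with the lowest MKI67 levels and transcript length slopes from the others and points to a structure of the samples besides treatment. In the other comparisons 1 split, the real one, called as many, and the highest other called 0 genes. Mixed splits hold the difference between the groups as spread within them, so these low counts do not test chance. The real counts against DMSO were 6073 for THZ1 4 h, 11009 for THZ1 24 h and 3140 for YKL-5-124 24 h. Between compounds they were 4827 at 4 h and 10959 at 24 h, and between times 9691 for THZ1 and 3061 for YKL-5-124.

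The 4657 genes called higher after 24 h of THZ1 stood beside 6352 called lower, in libraries whose make-up had changed. Of the higher calls, 48.6% were also higher calls under library totals and 12.3% with ribosomal protein mRNAs as the reference. Each setting moved all genes by about the same amount (log2 median −1.12, SD 0.0809, and median −2.18, SD 0.156), so these shares follow from the sizes of the shifts and do not test the TMM assumption that most genes did not change. That assumption and a rise beyond that of ribosomal protein mRNAs cannot be told apart from these values, since no measure of RNA per cell was used here.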

How the results depend on the processing

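The covariate for transcript length and the ribosomal protein reference are tests chosen after seeing the data; the other alternatives were planned. Of 362 values of counts and slopes under alternatives, 284 stayed within 1.5 times the reported count or within the spread and 78 moved. Of 6527 values for 342 named gene results, 6066 kept direction and side of the threshold, 416 lost the call, 7 gained one and 38 reversed. Reversed means a change of sign, whether or not the gene was called in the new direction. Of 792 values for 198 set tests, 726 kept their side, 45 lost the call, 38 of them with an estimated correlation, and 21 gained one. No count moved by over 1.5 times with the CPM filter, without mitochondrial genes, for protein-coding genes only or under upper-quartile factors. The cause was not tested except where the alternative's own construction, such as fewer samples or a fold threshold, gives it. At this depth and with 3 libraries per group, the simulated recovery of 1.5-fold changes was 8.57% to 28.8%. Few genes were changed in that simulation, which makes the adjusted threshold stricter than where many genes change. In the real THZ1 4 h comparison with DMSO, only 107 of the 2441 higher calls were at least 2-fold, so smaller changes were called there. Small changes can still be missed, but the share missed in the real comparisons was not measured.

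Under library totals, higher calls numbered 588 for THZ1 4 h and 2261 for THZ1 24 h against DMSO, and lower calls 103 for YKL-5-124 4 h. Higher and lower calls were 2096 and 1186 for YKL-5-124 24 h. They were 1992 and 9918 for THZ1 against YKL-5-124 at 24 h and 2284 and 8163 for THZ1 24 h against 4 h. They were 2288 and 1046 for YKL-5-124 24 h against 4 h, and 1556 and 7902 for the interaction. THZ1 against YKL-5-124 at 4 h had 202 higher calls. At THZ1 24 h, BIRC5 (−0.00862), FANCI (−0.17), ATM (−0.55), NPM1 (−0.15), SUPT5H (−0.15) and ERCC2 (−0.56) reversed.

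With ribosomal protein mRNAs as the reference, higher and lower calls were 29 and 5502 for THZ1 4 h, 572 and 11708 for THZ1 24 h and 5074 and 196 for YKL-5-124 24 h against DMSO, with 3 higher calls for YKL-5-124 4 h. THZ1 against YKL-5-124 had 25 higher calls at 4 h and 275 and 12942 calls at 24 h. Calls at 24 h against 4 h were 749 and 10369 for THZ1 and 6742 and 127 for YKL-5-124, and 197 and 11345 for the interaction. At THZ1 4 h, NUF2 (−0.0895), ECT2 (−0.18), FANCI (−0.11), RPA1 (−0.0267), NCL (−0.0135), NELFE (−0.20) and KRT8 (−0.13) reversed. At THZ1 24 h it was FOXM1 (−1.002), BIRC5 (−1.05), FANCI (−1.24), ATM (−1.65), TIMELESS (−0.20), RPA1 (−0.56), SPATA18 (−0.62), BID (−0.67), BAD (−0.96), OAS3 (−0.71), SRM (−0.37), NPM1 (−1.19), SUPT5H (−1.22), ERCC2 (−1.62), HSP90AA1 (−0.24), SREBF2 (−0.19), DHCR7 (−0.38), RGS5 (−0.37) and SERPINA1 (−0.16). At YKL-5-124 24 h it was CENPA (0.0127), SGK1 (0.0584), LARP7 (0.10) and HSPD1 (0.0644), and between the compounds at 24 h COL1A1 (−0.87) and SERPINA1 (−0.67).

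With the transcript length slope as a covariate, higher calls numbered 4173 for THZ1 4 h against DMSO and 3666 for THZ1 against YKL-5-124 at 4 h. Higher and lower calls were 404 and 863 for YKL-5-124 4 h, 2663 and 3642 for YKL-5-124 24 h and 2752 and 3509 for YKL-5-124 24 h against 4 h. Measured from each group's mean, the slope takes up spread within groups and cannot remove a difference between them. At a change of at least 2-fold, 107 were higher for THZ1 4 h, 5 and 29 called for YKL-5-124 4 h. At that size 591 and 355 were called for YKL-5-124 24 h, 60 and 2080 for THZ1 against YKL-5-124 at 4 h, and 571 and 322 for YKL-5-124 24 h against 4 h. Shared calls at that size were 26 for the compounds at 4 h, 440 at 24 h, 1980 for THZ1 and 10 for YKL-5-124 at both times. DESeq2 called 69 and 279 for YKL-5-124 4 h and 2747 higher for THZ1 against YKL-5-124 at 4 h over all genes it tested (2722 among the genes past the filter), where RLE factors gave 2536. With no filter beyond 1 count, YKL-5-124 4 h had 39 and 151 calls. With only the groups compared in the fit it had 1 and 16, and THZ1 against YKL-5-124 at 4 h had 1032 higher calls. Exonic length in place of span gave a slope difference of −0.913 at 24 h.

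The replicate numbers of the labels were not taken to pair the libraries, which would need every pair of the same number to correlate. Of 30 pairs of the same number, 18 had deviations correlated above 0.1, from −0.427 to 0.487, and 8 of 15 libraries were closest to their own number. The median was 0.199, against −0.137 for other pairs. All 10 pairs of number 1 exceeded 0.1, and the 5 libraries of that number had transcript length slopes below 0, as did 2 of the other 10, so a shared factor for that number stays open. With the replicate block, YKL-5-124 4 h had 18 higher and 146 lower calls, no other count moved by over 1.5 times, all 342 named gene results kept their call, and 5 set tests gained and 4 lost theirs.

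Leaving out each library in turn gave 2 to 9 higher and 12 to 68 lower calls for YKL-5-124 4 h. These were 3 and 30 without DMSO replicate 1, 2 and 22 without DMSO replicate 3, 2 and 12 without YKL-5-124 4 h replicate 2, and 3 and 23 without YKL-5-124 4 h replicate 3. YKL-5-124 24 h had 764 to 1218 higher and 1173 to 2016 lower calls, lowest without DMSO replicate 3, with 1214 lower without DMSO replicate 1. THZ1 against YKL-5-124 at 4 h had 999 to 1538 higher calls, 999 without THZ1 4 h replicate 3 and 1011 without YKL-5-124 4 h replicate 3. YKL-5-124 24 h against 4 h had 871 to 1020, 871 without YKL-5-124 4 h replicate 3 and 879 without YKL-5-124 24 h replicate 2. The other counts stayed within 1.5 times.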

Other observations

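The tests of the MKI67 spread in this part were chosen only after the result was seen, and those of gene span were planned. After 4 h of THZ1, stress and metabolic lists went both ways. Of 20 heat shock genes 10 rose and 5 fell (11 and 5 adjusted over the list alone), at 4 and 7 under library totals and 0 and 7 against ribosomal protein mRNAs. The transcription factor HSF2 fell (−1.27 ± 0.18). Of 24 cholesterol synthesis genes 9 rose and 5 fell (9 and 5 adjusted over the list alone), at 1 and 6 under library totals and 0 and 10 against ribosomal protein mRNAs. INSIG1, which retains the SREBP activator in the endoplasmic reticulum, fell (−1.36 ± 0.18). Of 22 hypoxia and glycolysis genes 11 rose and 6 fell (11 and 7 adjusted over the list alone), at a median of 0.35 and a mean of −0.25, and at 4 and 9 under library totals and 0 and 9 against ribosomal protein mRNAs. Among its falls was ADM, from 307 ± 32.5 to 12.4 ± 0.743 CPM (mean ± SD, n = 3 libraries each). GATA4, a transcription factor of the epithelial list, fell too (−2.58 ± 0.24). None of these first 3 lists was called by camera with Benjamini-Hochberg adjustment (adjusted p = 0.239, 0.33 and 0.874).

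From 4 h to 24 h of YKL-5-124, 10 of 14 replication-dependent histones rose and 0 fell (10 and 1 adjusted over the list alone), at a median of 2.31, though single histone genes are uncertain. Of 24 cholesterol synthesis genes 15 rose and 0 fell (17 and 0 adjusted over the list alone), and of 21 NF-kB targets 10 and 0 (14 and 0 adjusted over the list alone). These lists were called higher by camera with Benjamini-Hochberg adjustment (adjusted p = 1.13e-18, 4.66e-18 and 3.38e-08; adjusted p = 0.0308, 0.0339 and 0.00619 with an estimated correlation). In the G1/S list 0 rose and 25 fell of 43 (0 and 30 adjusted over the list alone), and in ribosome biogenesis 0 and 18 of 31 (0 and 20 adjusted over the list alone), but against ribosomal protein mRNAs these turned to 7 and 5 and to 7 and 1. Both were called lower by camera with Benjamini-Hochberg adjustment (adjusted p = 5.95e-16 and 6.51e-08; adjusted p = 0.00609 and 0.00637 with an estimated correlation). Of 29 interferon-stimulated genes 6 rose and 2 fell at YKL-5-124 24 h against DMSO (7 and 3 adjusted over the list alone), at a median of −0.08 (0.07 under library totals) and a mean of 0.20. They included ISG15 (1.10 ± 0.25) and IFI6 (1.03 ± 0.13), both higher. The list was not called by camera with Benjamini-Hochberg adjustment (adjusted p = 0.26).

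MKI67 differed widely between libraries of the same group, and the design names no biological difference between them. The other 39 G2/M genes had a median slope of −0.00449 on MKI67 within groups (quartiles −0.0448 and 0.0584), which argues against proliferation, although CENPF, chosen after its value was seen, reached 0.356. A linear trend with transcript length and GC took away 18.03% of the MKI67 spread, which argues against that trend as the whole cause. The 886 other genes with transcripts over 8000 bases had a median slope of 0.0710, against −0.0864 for 1549 genes under 2000 bases, while the MKI67 transcript has 12678. Of the 886, 78.0% had a slope above 0. Across protein-coding genes, weights on the main axis of variation within groups had a Spearman correlation of 0.453 with transcript length. A library difference shared with long transcripts may take part and cannot be told apart, because the median slope lies between the bounds set for it after the data were seen.

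THZ1 is known also to bind CDK12 and CDK13, and loss of CDK12 is known to affect long genes, which gave the hypothesis that THZ1 lowers genes of long span more than YKL-5-124 does. At 4 h the slope of log2 change on log10 span was 0.316 ± 0.171 for THZ1 and 0.0421 ± 0.0843 for YKL-5-124 (SD, n = 3 libraries each), a difference of 0.274 opposite to the hypothesis (two-sided exact permutation test, p = 0.2). Lower calls at THZ1 4 h ran from 32.8% of the 3053 genes of shortest span to 18.4% of the 3053 of longest span. With transcript length and GC in the regression 162% of the difference stayed, which argues against these as its cause (0.444, exact permutation p = 0.1, the smallest that 3 against 3 can give). At 24 h the difference was −0.260 (exact permutation p = 0.1), but 0.254 with transcript length and GC, so its direction stays open.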
